A study of Mus musculus with 6 samples.

How the data were processed

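The samples were 6 stranded polyA RNA libraries of YFP-positive, DAPI-excluding cells sorted from dissociated mouse pancreas, 3 labelled Fra1KO and 3 labelled Fra1WT, prepared with a directional NEBNext kit per the labels' protocols. The deposited values are raw gene counts, 1 per gene and library. Reads were aligned to mm10 with STAR 2.7.10 per the submitters' processing notes, and the authors made the counts with featureCounts 2.0.3 and the GENCODE M23 primary assembly annotation, per the file headers. The same headers show that read pairs were counted over exons and summed by gene, on the reverse strand (setting 2), each assigned to the gene with the largest overlap, and that reads with several alignments were not asked for. Such counting keeps overlapping genes on opposite strands apart, and it underestimates genes with near-identical copies, so amylase, trypsinogen, Reg, immunoglobulin and pseudogene counts are uncertain. Trimming and read filters are not given in the sources used here.

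Each table holds 55421 genes, of which 55154 were given a symbol by their identifier. Gene types and untranslated regions came from GENCODE M21 on the same build. The 2 genes mapped in detail have the same start and end there and in the count tables. Groups and replicate numbers were taken from the sample titles. Library depth was 23905534 to 62253551 gene counts. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 48.3 to 536.3 over the genes tested) and none was a copy of another.

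Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15. Genes were kept by filterByExpr (14755 genes), libraries were scaled by TMM, and groups were compared with the edgeR quasi-likelihood test with robust dispersion, with group as the sole term and Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are the libraries labelled Fra1KO minus those labelled Fra1WT, their standard error is the size of the change over the square root of the F statistic, and CPM values are scaled by TMM. Scores are the mean log2 CPM of a list, with a prior count of 1. The 27 gene lists, for acinar, ductal, metaplastic and signalling programmes, handling stress and the other cell types of a dissociated pancreas, were fixed before the data were examined, and 26 had at least 3 genes to test. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. The enzyme share was compared with an exact two-sided permutation test, and shares of single libraries carry 95% Wilson intervals.

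Genes named in the text followed a rule also fixed beforehand. It took Fosl1 and the AP-1 list, and the 10 genes with the largest log2 fold change in each direction among those past the threshold, with groups that did not overlap, a mean of at least 5 CPM in the higher group and a descriptive symbol. It also took up to 4 members of each list with the smallest adjusted p, and up to 2 with the highest CPM from each list of another cell type. Further members of a list that passed are given as a count, or named where few passed, and genes outside the rule are said to have been singled out after their values were seen.

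Alternatives covered other scalings (DESeq2 size factors, upper quartile, library totals alone, and TMM without enzymes and mitochondrial genes), no filter or a stricter filter (1 CPM in 3 samples), DESeq2, limma-voom with and without library weights, the replicate number as a block, an adjusted p under 0.01, a test against a fold change of 1.5, and leaving out each library in turn. A fit of protein-coding genes alone was added after seeing the data. The pipeline was tested on counts simulated for this comparison, with 14755 genes of which 200 were changed, and 14250 genes passed the filter. It recovered 6 of 67 1.5-fold (9.0%), 27 of 67 2-fold (40.3%) and 54 of 66 4-fold changes (81.8%). It also called 13 unchanged genes, a larger share of its calls than the threshold of 0.05 allows for. It called 0 of 27 random lists, whose genes were simulated independently of each other. No gene or sample in the tables was left out of the analysis other than by the filter.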

Results

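PolyA RNA was sequenced from acinar-lineage cells of mouse pancreas, collected on day 5 after acute pancreatitis. The mice carried a tamoxifen-inducible Cre driven by Ptf1a (a transcription factor of acinar cells), an oncogenic Kras allele and a YFP reporter. In 1 group they also carried floxed alleles of Fosl1, the gene that encodes the AP-1 transcription factor Fra1. Its 3 libraries are labelled Fra1KO, and the 3 libraries from mice without the floxed alleles are labelled Fra1WT. Mice of 7 to 8 weeks received tamoxifen and, 1 week later, 8 hourly injections a day of 150 µg/kg caerulein, a secretagogue that inflames the pancreas, for 2 days. YFP-positive cells that excluded DAPI were then sorted. Counts assigned to genes numbered 50299842, 62253551 and 27633347 in the libraries labelled Fra1KO and 32914089, 23905534 and 32399820 in those labelled Fra1WT. The comparison addresses how acinar-lineage cells that express oncogenic Kras differ after injury when Fosl1 is targeted, as they change from acinar towards ductal identity. The labels do not state outright that each library came from a separate mouse, so p-values measure the spread between these samples.

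The targeted gene went against the group labels. Fosl1 (ENSMUSG00000024912.6, mm10 chromosome 19, 5447547 to 5455946, forward strand) was higher in the libraries labelled Fra1KO, at 5.24 ± 0.79 CPM (counts relative to the TMM-scaled library size; SD, n = 3), than in those labelled Fra1WT, at 1.90 ± 0.88 CPM (SD, n = 3). It was counted 285, 639 and 165 times in the libraries labelled Fra1KO and 80, 34 and 20 times in those labelled Fra1WT. The log2 fold change was 1.45 ± 0.34 (SE; edgeR quasi-likelihood test, adjusted p = 0.042), with the 3 values of each group apart from those of the other. The call ended when any 1 of 5 libraries was left out. Adjusted p was 0.0671, 0.0511 and 0.0731 without Fra1KO replicate 1, 2 or 3, and 0.136 and 0.1 without Fra1WT replicate 2 or 3, with log2 fold changes between 1.14 and 1.56. The count pools 4 separate exon blocks of the gene, and the labels do not say which of them the floxed alleles remove, so the count alone does not check the deletion. Ccdc85b (ENSMUSG00000095098.2, chromosome 19, 5453180 to 5457894) lies on the reverse strand, and its 3' untranslated region (5453180 to 5456791) spans the last 2 of these blocks. Singled out after its values were seen, it was lower in the libraries labelled Fra1KO, at 6.23 ± 0.99 against 13.2 ± 1.29 CPM (SD, n = 3; log2 fold change -1.09 ± 0.19, adjusted p = 0.0223). Directions below are those of the labels.

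**Figure D1:**
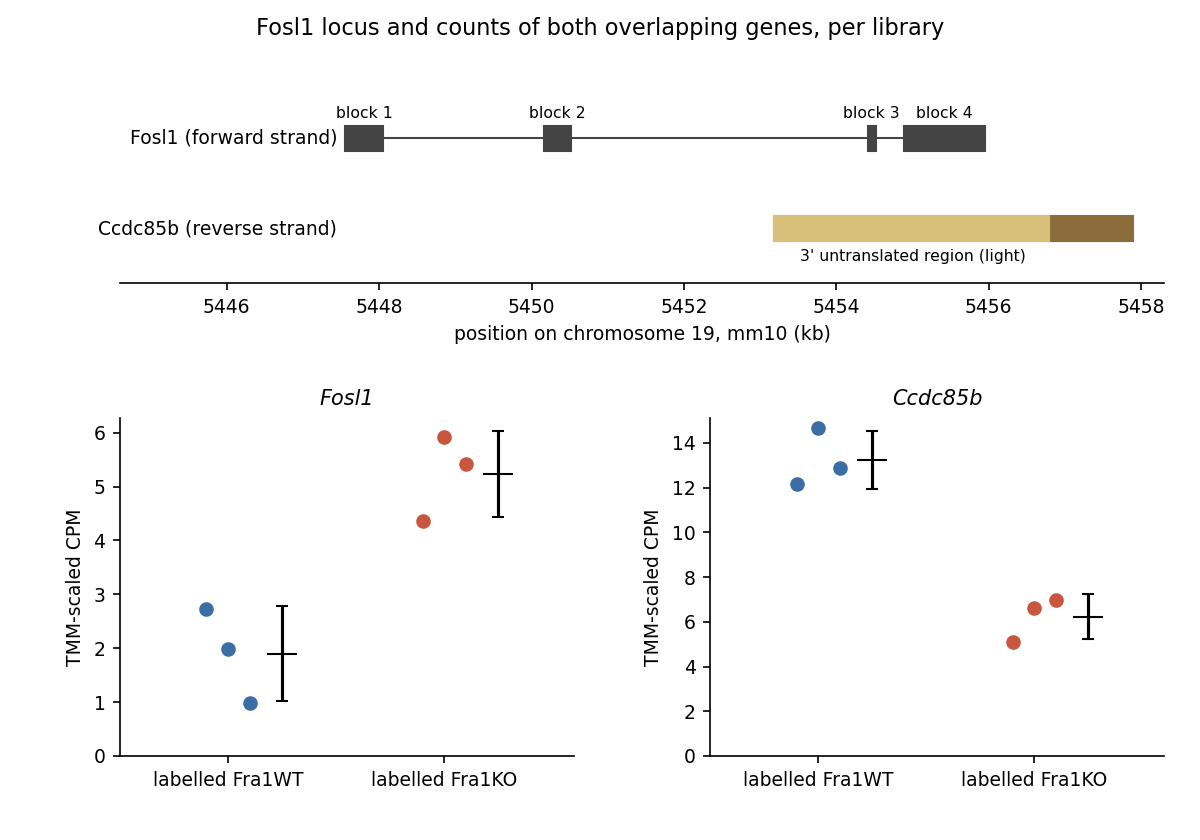
Map of Fosl1 and Ccdc85b on chromosome 19 (mm10, position in kb; boxes, exon blocks; light box, the 3' untranslated region of Ccdc85b) above their TMM-scaled CPM per library (points, 3 per group; bar, mean ± SD). Fosl1 lay between 4.37 and 5.92 CPM in the libraries labelled Fra1KO and between 0.979 and 2.72 in those labelled Fra1WT, and Ccdc85b between 5.10 and 6.96 against 12.2 and 14.7.

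Among 14755 genes tested, 533 were higher and 530 lower in the libraries labelled Fra1KO (edgeR, adjusted p under 0.05). The even split depends on the scaling, and library totals alone gave 8048 higher and 134 lower. TMM factors did not overlap between the groups, at 1.30, 1.74 and 1.10 in the libraries labelled Fra1KO and 0.893, 0.714 and 0.631 in those labelled Fra1WT. Procr, the endothelial protein C receptor (ENSMUSG00000027611.12, chromosome 2, 155751117 to 155755471), had 86.9 ± 21.3 CPM against 11.5 ± 3.22 (SD, n = 3; log2 fold change 2.92 ± 0.26, adjusted p = 0.00166). Sox11, a transcription factor of developing tissues, had 5.76 ± 0.44 against 0.472 ± 0.26 CPM (log2 fold change 3.64 ± 0.36, adjusted p = 0.00252). The other genes with the largest rises included Inhba (an activin subunit), Gem (a small GTPase), Flrt3, Rgs17, Kcnj15, Oasl2 and Prss22 (a serine protease), with log2 fold changes between 2.16 and 2.64. The largest falls included Syt15 (a synaptotagmin), at 1.54 ± 0.51 against 13.1 ± 1.78 CPM (log2 fold change -3.06 ± 0.27, adjusted p = 0.00143), and Tdh (threonine dehydrogenase), at 5.36 ± 3.35 against 50.6 ± 15.6 CPM. Scn4b (a sodium channel subunit), Cldn9 (a claudin), Galnt6os, Rnf225, Amy2b and Cdo1 (cysteine dioxygenase) were also among them, with log2 fold changes between -4.97 and -2.73. Processed pseudogenes also stood at both ends. Rps2-ps13 had 1, 5 and 1 counts in the libraries labelled Fra1KO against 7234, 4569 and 5654, Ftl2-ps had 4321, 9766 and 2830 against 1, 2 and 0, and Atp6v0c-ps2 had 17, 35 and 4 against 218, 95 and 115. Their counts are uncertain, since such copies can share reads with their parent genes. Of 3 parents singled out after their values were seen, Ftl1 fell (log2 fold change -1.28 ± 0.21, adjusted p = 0.0194), while Rps2 (0.38 ± 0.22, adjusted p = 0.27) and Atp6v0c (0.34 ± 0.14, adjusted p = 0.141) did not pass.

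The number of changed genes rested on several libraries. The 1063 genes became 26 without Fra1WT replicate 2, 81 without Fra1WT replicate 3, 167 without Fra1KO replicate 1 and 626 without Fra1WT replicate 1. Each of the 1063 kept its sign in each of these fits. That was nearly fixed in advance, since the groups did not overlap for any of the 1063. Of 81 genes past the threshold that the naming rule gave, 10 stayed past it whichever library was left out: Procr, Sox11, Ftl2-ps, Rps2-ps13, Atp6v0c-ps2, Scn4b, Syt15, Plat, Hbegf and Jchain. The others lost their call in at least 1 of the 6 fits, and 4 of them, Muc6, Ifit1, Aen and Hk2, in each of the 6. Without Fra1KO replicates 1, 2 and 3 in turn, 30, 66 and 62 of the 81 stayed past it, and without Fra1WT replicates 1, 2 and 3, 53, 10 and 34. The groups did not overlap for 5373 genes (36.4%), where chance gives 10% on average. Genes that move together can take a single division far from that average, and the share in the other divisions was not computed. Fra1KO replicate 1 was the only library with the transcripts of a female, with 29035 counts of Xist against at most 9 in any other library and 0 of the Y-linked Ddx3y, both singled out after their values were seen.

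Acinar enzyme transcripts were less abundant in the libraries labelled Fra1KO. The 29 listed enzymes and secretory proteins took 44.1%, 26.6% and 48.1% of gene counts there and 56.2%, 61.7% and 64.7% in the libraries labelled Fra1WT, with 95% Wilson intervals at most 0.039 points wide, which cover counting error only. The means were 39.6 ± 11.4% and 60.9 ± 4.35% (SD, n = 3; exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows). All 29 had negative log2 fold changes (median -1.47), and 3 fell past the threshold over all genes: Amy2b (an amylase locus annotated as an unprocessed pseudogene, -4.12 ± 0.79, adjusted p = 0.0368), Pnlip (pancreatic lipase, -2.40 ± 0.62, adjusted p = 0.0469) and Pla2g1b (a secreted phospholipase, -2.40 ± 0.45, adjusted p = 0.0313). Adjusted over the list alone, 26 fell, and in a fit of protein-coding genes alone, added after seeing the data, 2 fell past the threshold over all genes. That number was 20 without an expression filter, 15 under limma-voom with library weights, and 0 without Fra1KO replicate 1 or Fra1WT replicate 2 or 3. Amylase, trypsinogen and Reg genes have near-identical copies, so their single values are uncertain. Of 10 acinar transcription factors measured, Foxa3 fell (-0.63 ± 0.15, adjusted p = 0.0424), also the 1 call adjusted over the list alone, while Bhlha15, which sets secretory architecture, had 110 ± 72.5 against 306 ± 88.2 CPM (adjusted p = 0.141) and Rbpjl, a partner of Ptf1a, 240 ± 121 against 438 ± 55.3 CPM (adjusted p = 0.174). Of 24 endoplasmic reticulum stress genes, Pdia2 (a pancreatic disulfide isomerase), Asns and Sec61b fell, and 4 fell when adjusted over the list alone. Of 7 Reg family and pancreatitis-associated genes, Nupr1 (a stress-response factor) fell (-0.99 ± 0.24, adjusted p = 0.0427), the 1 call adjusted over the list alone as well, and Reg1 stood at 14614 ± 4811 against 27396 ± 3139 CPM (adjusted p = 0.16). As sets (camera), these 4 lists lay lower, with adjusted p of 1.16e-17 (enzymes), 0.0253 (transcription factors), 0.000851 (endoplasmic reticulum stress) and 0.0229 (Reg family). With an estimated correlation, the adjusted p was 0.25, 0.413, 0.567 and 0.439. The transcription factor call ended without Fra1KO replicate 2 (adjusted p = 0.0557) and on library totals alone (0.0828). That of the Reg family ended without Fra1KO replicate 1 or 2 (0.0535 and 0.0749), without Fra1WT replicate 1 or 2 (0.0706 and 0.0962) and under limma-voom with library weights (0.0738).

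A few ductal genes rose. Of 27 measured, Slc4a4 (a bicarbonate transporter, log2 fold change 1.76 ± 0.28, adjusted p = 0.0193), Cldn4 (a tight junction protein, 1.81 ± 0.36, adjusted p = 0.0331) and Glis3 (0.85 ± 0.22, adjusted p = 0.0475) rose, 24 did not pass, and 8 rose and 1 fell when adjusted over the list alone. The set lay higher (camera, adjusted p = 0.000385; adjusted p = 0.439 with an estimated correlation). Of 17 gastric and pyloric metaplasia genes, the mucin Muc6 (10.8 ± 4.97 against 60.6 ± 43.4 CPM), the trefoil peptide Tff2 (725 ± 324 against 1784 ± 259 CPM) and Vsig2 fell (adjusted p = 0.0492, 0.0455 and 0.0379), and 1 rose and 4 fell when adjusted over the list alone. That set did not pass (camera, adjusted p = 0.15; 0.765 with an estimated correlation), but passed as lower without Fra1KO replicate 3 (0.0134) or Fra1WT replicate 2 or 3 (0.0401 and 0.0117) and on library totals alone (0.00134). Without Fra1WT replicate 1 its median turned from -0.40 to 0.12 and no member was called (camera, adjusted p = 0.736). Of 16 tuft cell genes listed, 8 had enough counts to test, and Pou2f3 was not among them. Trpm5, an ion channel of tuft cells, fell (0.177 ± 0.05 against 1.97 ± 1.92 CPM, log2 fold change -3.43 ± 0.70, adjusted p = 0.0328). Dclk1, the most abundant of the 8, went the other way without passing (20.0 against 10.4 CPM, log2 fold change 0.94, adjusted p = 0.237). Log2 fold changes were positive for 3 of the 8 and negative for 5, and 2 fell when adjusted over the list alone. The set did not pass (camera, adjusted p = 0.373, and 0.788 with an estimated correlation). Fra1WT replicate 1 had 4.19 CPM of Trpm5 and the other Fra1WT libraries 0.997 and 0.734, and without it the log2 fold change was -2.22 (adjusted p = 0.0635); the call held in 2 of the 6 fits with 1 library left out.

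Among the 26 lists tested, 4 of signalling and matrix genes had the most members that rose. Over all 14755 genes tested 533 rose, and these lists hold only a part of them. Of 31 NF-kB, cytokine and chemokine genes, 13 rose and none fell, among them Csf2 (a myeloid growth factor, log2 fold change 3.48 ± 0.45, adjusted p = 0.00938), Lif (2.00 ± 0.26, adjusted p = 0.0103), Tnfaip3 (an NF-kB inhibitor, 1.53 ± 0.20, adjusted p = 0.00942) and Ptgs2 (a prostaglandin synthase). Adjusted over the list alone, 26 rose. Of 26 laminin, integrin and pericellular protease genes, 12 rose, among them Plat (tissue plasminogen activator, 29.1 ± 4.75 against 8.00 ± 1.86 CPM, adjusted p = 0.00427), Lamb1 (a laminin chain, 1.56 ± 0.21, adjusted p = 0.00942), Mmp14 and Serpine1, and 22 rose when adjusted over the list alone. Of 24 KRAS-MAPK output and feedback genes, 7 rose, led by Hbegf (an EGF receptor ligand, 64.4 ± 11.8 against 20.1 ± 2.05 CPM, adjusted p = 0.00366) with the phosphatases Dusp5 and Dusp6, and Ier3. Adjusted over the list alone, 16 rose. Of 15 YAP/TEAD targets, 6 rose (11 when adjusted over the list alone), among them Ccn1 (97.9 ± 11.2 against 41.7 ± 2.20 CPM, adjusted p = 0.00942), Ankrd1, Arhgef17 and Lats2. The camera adjusted p values of these 4 sets were 1.02e-16, 1.7e-14, 2.67e-09 and 6.58e-09, and 0.225, 0.25, 0.225 and 0.225 with an estimated correlation.

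**Figure D2:**
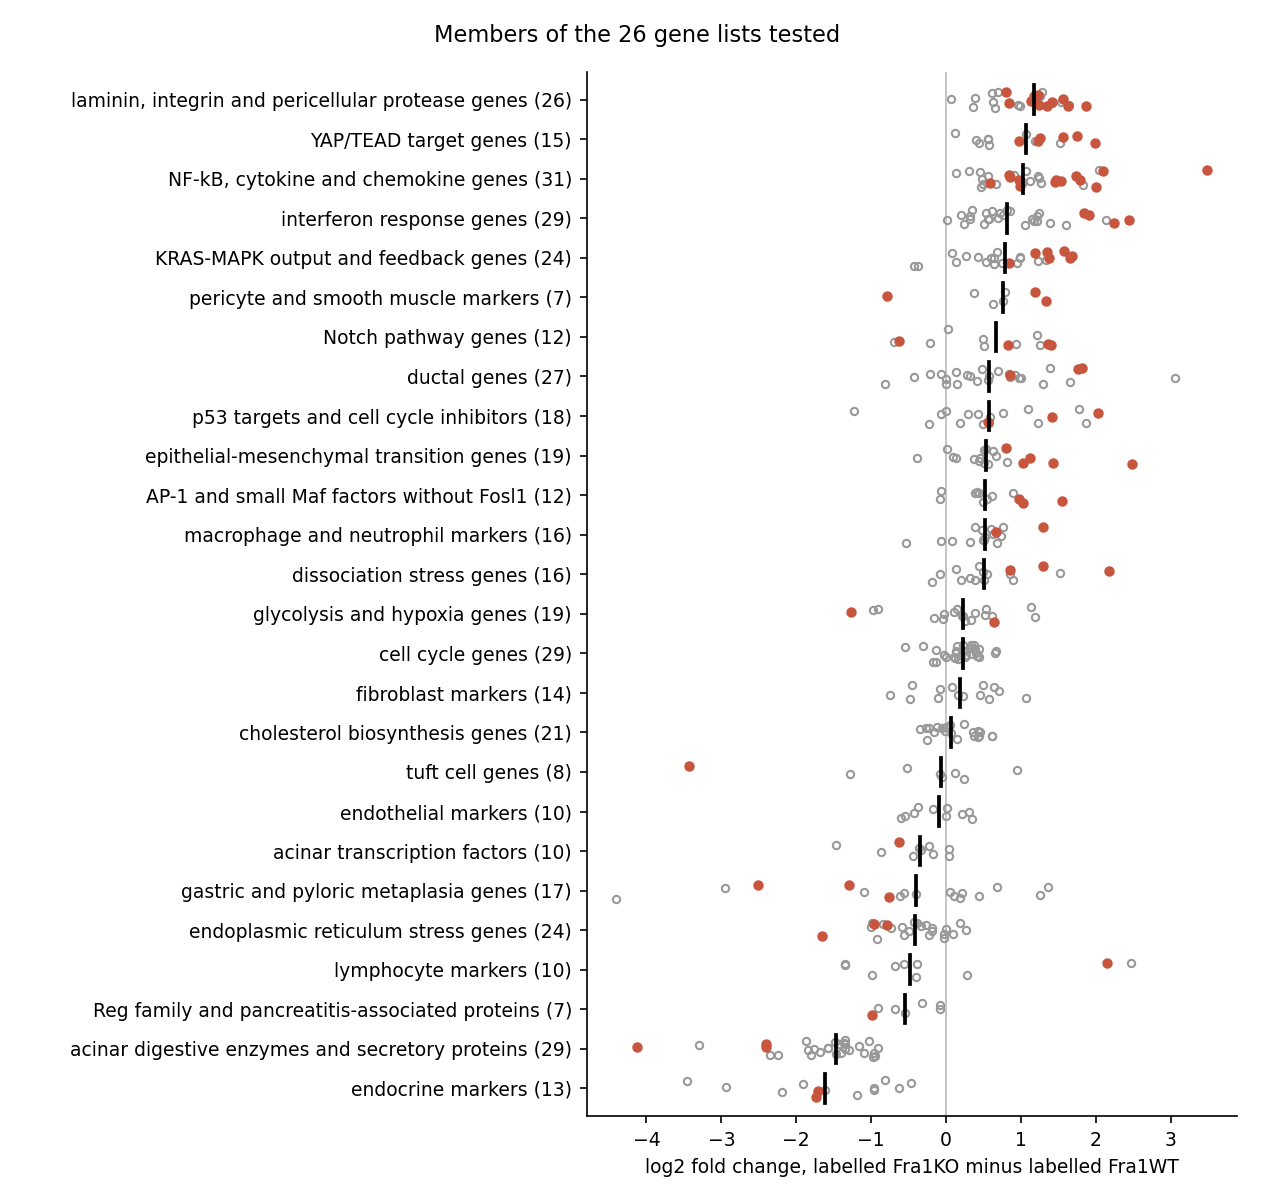
Log2 fold change (libraries labelled Fra1KO minus Fra1WT, n = 3 each) of each measured member of the 26 gene lists tested, ordered by the median (black bar); filled points passed adjusted p under 0.05 over all genes, open points did not, and the number of members is in parentheses. Medians ran from -1.62 for endocrine markers and -1.47 for acinar enzymes to 1.17 for laminin, integrin and pericellular protease genes.

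A minority of the other AP-1 and small Maf factors rose past the threshold, though 10 of the 12 measured had positive log2 fold changes. Maff (21.2 ± 1.65 against 10.5 ± 1.83 CPM, adjusted p = 0.0215), Fosl2 (56.7 ± 3.16 against 29.0 ± 7.39 CPM, adjusted p = 0.0313) and Jdp2 (3.44 ± 0.78 against 1.20 ± 0.37 CPM, adjusted p = 0.0331) rose, and 5 rose when adjusted over the list alone. The log2 fold changes of Fos, Junb, Jun and Jund were 0.44, 0.49, -0.08 and -0.07 and did not pass. Those of Atf3, Mafg, Fosb, Mafk and Batf lay between 0.39 and 0.89 and did not pass either. For Jun and Jund they were positive when counts were scaled by library totals alone. Of 29 interferon response genes, Cxcl10, Oasl2, Ifit3 and Ifit1 rose by 1.84 to 2.44 on the log2 scale (15 adjusted over the list alone). Of 19 epithelial-mesenchymal transition genes, 5 rose: Fn1 (fibronectin, 347 ± 19.8 against 129 ± 22.9 CPM, adjusted p = 0.0105), Cdh2, Tgfb1, Itga5 and Tnc, the last of these outside the naming rule and named after its values were seen (7 adjusted over the list alone). Of 12 Notch pathway genes, Hes1 (1.39 ± 0.23, adjusted p = 0.0193), Jag1 and Nrarp rose and Lfng fell (6 rose and 2 fell when adjusted over the list alone). Of 18 p53 targets and cell cycle inhibitors, Cdkn1a (79.3 ± 12.2 against 29.8 ± 5.18 CPM, adjusted p = 0.00942), Pmaip1 and Aen rose (11 rose and 1 fell when adjusted over the list alone). The camera adjusted p values of the AP-1, interferon, epithelial-mesenchymal, Notch and p53 sets, all higher, were 0.000851, 1.45e-08, 2.95e-05, 0.0294 and 0.000148. With an estimated correlation, the adjusted p was 0.225 for 4 of them and 0.25 for the interferon set. The Notch call ended without Fra1WT replicate 2 (adjusted p = 0.0659) and under limma-voom (0.0667).

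Cell cycle genes (29 measured) and cholesterol biosynthesis genes (21 measured) had no member past the threshold of the main edgeR fit, over all genes or adjusted over the list alone, and none by DESeq2 or limma-voom. Scaling by library totals alone called 25 and 10 as higher, and the fit without an expression filter called 1 cell cycle gene. At an unadjusted p under 0.05 there were 3 and 0. Bub1, a mitotic checkpoint kinase, had 4.70 ± 1.29 against 2.97 ± 0.44 CPM (adjusted p = 0.13), and Hmgcr, the rate-limiting enzyme of cholesterol synthesis, 38.2 ± 13.7 against 24.8 ± 7.82 CPM (adjusted p = 0.204). The cell cycle set passed as higher only without Fra1KO replicate 1 (camera, adjusted p = 0.0381, against 0.178 in all 6 libraries; 0.822 with an estimated correlation), and the cholesterol set did not pass (0.674; 0.907 with an estimated correlation). Of 19 glycolysis and hypoxia genes, Hk2 (hexokinase, 0.64 ± 0.15, adjusted p = 0.0396) rose and Pdk1 (-1.27 ± 0.27, adjusted p = 0.0379) fell (2 rose and 1 fell when adjusted over the list alone; camera, adjusted p = 0.318; 0.765 with an estimated correlation).

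Some markers of other cells and of handling changed between the groups too. Of 16 macrophage and neutrophil markers, Itgam (5.20 ± 0.63 against 2.11 ± 0.54 CPM) and C1qc (20.3 ± 1.05 against 12.9 ± 0.62 CPM) rose (9 adjusted over the list alone), and Lyz2, their most abundant member, had 127 ± 17.2 against 82.8 ± 4.48 CPM (adjusted p = 0.0556). Of 10 lymphocyte markers, the plasma cell gene Jchain rose (8.05 ± 1.95 against 1.79 ± 0.19 CPM, adjusted p = 0.00528), 2 rose when adjusted over the list alone, and the T cell gene Cd3e had 0.242 against 0.617 CPM (adjusted p = 0.0955). The median of that list was -0.48 while its set test pointed up without passing (camera, adjusted p = 0.722; 0.907 with an estimated correlation). Under the stricter filter the median was 1.21 and the set passed as higher (0.0104), and the median was 0.07 without Fra1WT replicate 1 and -0.86 without Fra1WT replicate 2. Of 13 endocrine markers, Ttr and Pcsk1 fell (5 adjusted over the list alone). Of 7 pericyte and smooth muscle markers, Tagln and Acta2 rose and Rgs5 fell (2 rose and 1 fell when adjusted over the list alone), and no fibroblast (14 measured) or endothelial (10 measured) marker passed by either adjustment in the main edgeR fit or by limma-voom without library weights. Fibroblast markers called as higher in other settings numbered 1 with library weights, with the replicate block, without Fra1KO replicate 2 and without Fra1WT replicate 1, 4 without an expression filter and 9 on library totals alone, where 4 endothelial markers were called as well. At an unadjusted p under 0.05 there were 6 and 1, and DESeq2 called 2 and 0. The collagen genes Col1a1 and Col3a1, the most abundant of the fibroblast markers, had 306 ± 71.2 and 437 ± 102 against 205 ± 55.4 and 393 ± 39.3 CPM. Of 16 dissociation stress genes, the heat shock genes Hsph1 and Hspa1a and the phosphatase Dusp1 rose (6 adjusted over the list alone). This list shares Fos, Fosb, Jun, Junb and Atf3 with the AP-1 list and Egr1 with the KRAS-MAPK list. The acinar transcription factor and endoplasmic reticulum stress lists share Xbp1, and the epithelial-mesenchymal and YAP/TEAD lists share Axl. Sets that share members are not independent. The macrophage, dissociation and endocrine sets passed, the first 2 higher and the last lower (camera, adjusted p = 0.000441, 0.00061 and 2.95e-05; 0.225, 0.352 and 0.335 with an estimated correlation). The pericyte, fibroblast and endothelial sets did not (0.0576, 0.373 and 0.573; 0.25, 0.822 and 0.867 with an estimated correlation), though the pericyte set passed without Fra1KO replicate 1 (0.0381) or 2 (0.0141) or Fra1WT replicate 2 (0.0152) or 3 (0.02), without an expression filter (0.0064), on library totals alone (0.0427) and by fry (0.045), and the fibroblast set without Fra1KO replicate 2 (0.00825). The erythroid list had no member with enough counts to test.

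**Figure D3:**
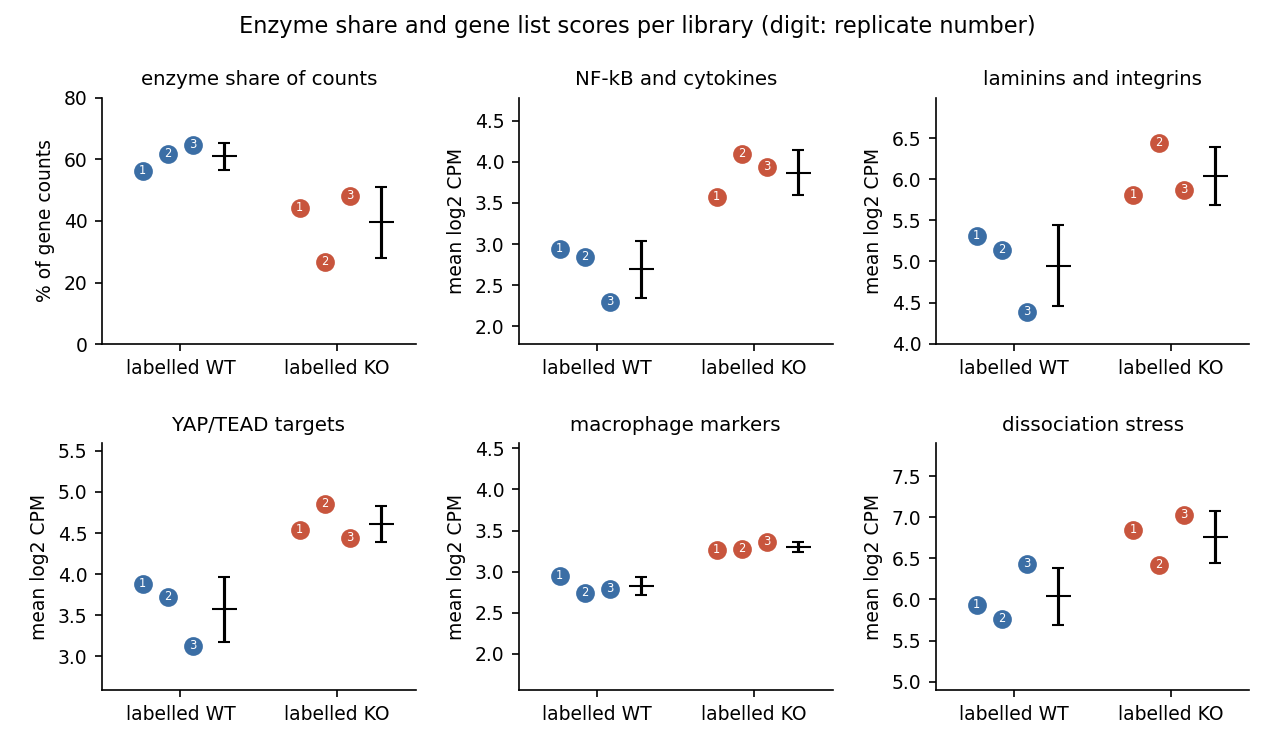
Share of gene counts from the 29 acinar enzymes and secretory proteins (%, axis from 0) and mean TMM-scaled log2 CPM of 5 gene lists (each axis spans the same 3 log2 units) per library, with the replicate number in each point and the mean ± SD (n = 3) as a bar. The enzyme share of Fra1KO replicate 2 (26.6%) lay lowest, macrophage scores did not overlap between the groups, and dissociation stress scores did, with Fra1WT replicate 3 (6.43) above Fra1KO replicate 2 (6.41).

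In all, camera with a preset correlation called 17 of the 26 lists tested, none held with an estimated correlation (smallest adjusted p = 0.225), and fry, which asks whether a set moves on balance one way, called 10, of which 9 were among the 17. Those that fry did not call were the acinar enzymes and the laminin list (adjusted p = 0.0543 for each), the ductal, acinar transcription factor and Reg lists (0.132 for each), endoplasmic reticulum stress (0.21), dissociation stress (0.102) and endocrine markers (0.0871). Each of the other divisions of the 6 libraries into 3 and 3 gave 11 to 18 lists called by camera, so the number of called lists does not set the groups apart from other divisions. Scaling by library totals alone moved the median log2 fold change of all genes to 0.92. Under it the medians of the acinar transcription factor (0.48), gastric (0.38), endoplasmic reticulum stress (0.40), Reg (0.25), tuft (0.75), lymphocyte (0.34) and endothelial (0.77) lists turned positive while each stayed below that of all genes.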

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

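The fit of protein-coding genes alone was chosen after seeing the data; the other settings were fixed before the data were examined. Scaling by library totals alone, which moved the median log2 fold change of all genes to 0.92, called 8182 genes, 8048 higher (98.4%) and 134 lower, against 1063, 533 (50.1%) and 530. It also reversed 7 of the named genes, whose log2 fold changes became 0.25 (Foxa3), 0.78 (Jun), 0.82 (Jund), 0.26 (Lfng), 0.11 (Rgs5), 0.0696 (Sec61b) and 0.10 (Vsig2), each below the shift of all genes. The other scalings gave 1036 to 1075 genes. Without an expression filter 2492 genes passed (1398 higher, 1094 lower), with DESeq2 2468 (1151 and 1317), with limma-voom 698 (257 and 441) and with library weights 1401; the cause was not tested. An adjusted p under 0.01 left 31 (20 and 11) and a test against 1.5-fold left 34 (19 and 15), both stricter by construction. Protein-coding genes alone gave 1012. With 1 library fewer, 26 to 791 genes passed, 14 to 342 higher and 12 to 466 lower. Outside library totals alone, where 900 of the 1063 kept their sign, each of the 1063 that was tested kept it in each setting. With 1 library left out this was nearly fixed in advance, since the groups did not overlap for any of the 1063. The Fosl1 log2 fold change ranged from 1.14 to 1.83 with 1 library left out, and its call was lost under limma-voom (1.51, adjusted p = 0.0511; range over settings with all libraries 0.000105 to 0.0511). Lists called numbered 16 to 19, 0 with an estimated correlation and 10 with fry. The enzyme share difference ranged from -25.57 to -14.8 points with 1 library left out and was -21.51 without mitochondrial genes. No pairing by replicate number was seen: deviations from the group means correlated at -0.31, 0.11 and 0.29 for numbers 1, 2 and 3, and 2 of 6 samples correlated best with their own number. With so few libraries, such a check could miss a shared litter, sort or batch. With the replicate block 958 genes passed, 766 of them among the 1063, and Fosl1 had 1.51 (adjusted p = 0.0503). Of 1484 values of named genes in other settings, 54 lost and 84 gained a call, and of 816 with 1 library left out, 226 lost and 9 gained one. Of simulated 1.5-fold changes, 9.0% were recovered.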

Other observations

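The gene groups and tests in this part were chosen after the results were seen, except the counts over other divisions of the samples. Some transcripts of the respiratory chain fell in the libraries labelled Fra1KO. Of 13 protein-coding genes of the mitochondrial genome, 7 fell, among them mt-Atp6 (log2 fold change -1.27 ± 0.21, adjusted p = 0.0193) and mt-Nd4 (-1.07 ± 0.21, adjusted p = 0.0313), and the list had a median of -1.07 (camera, adjusted p = 5.11e-10 over 6 such lists; 0.135 with an estimated correlation). The share of counts from all genes of the mitochondrial genome was 0.929 ± 0.24% against 0.904 ± 0.12% (SD, n = 3; exact permutation p = 0.8), so the fall of the 7 is one relative to other genes after TMM. Of 83 nuclear respiratory chain genes, 10 fell, among them Atp5g1 (-1.05 ± 0.18, adjusted p = 0.0228), with a median of -0.46 (camera, adjusted p = 4.5e-12; 0.305 with an estimated correlation). Short genes lay lower in general: the median log2 fold change was -0.13 in the fifth of genes with the shortest annotated length and 0.12 in the fifth with the longest, and 57 of the 83 were in the former, with a median of -0.47 against -0.12 for its other genes.

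Some immunoglobulin genes rose, as Jchain did: of 24 measured, 7 rose and none fell, among them Igkc (1.82 ± 0.42, adjusted p = 0.046), with a list median of 1.75 (camera, adjusted p = 1.67e-07; 0.0653 with an estimated correlation). Their reads can be shared between family members. Of 9 class II MHC genes, which present antigen, H2-Aa (-0.96 ± 0.21, adjusted p = 0.0374) and H2-Ab1 (-0.92 ± 0.22, adjusted p = 0.0429) fell (camera, adjusted p = 0.00222; 0.258 with an estimated correlation). Of 10 Wnt ligands, Wnt7b (1.90 ± 0.33, adjusted p = 0.0247), Wnt7a and Wnt4 rose (camera, adjusted p = 0.0197; 0.258 with an estimated correlation). Among 16 circadian genes, Nr1d1 (-1.75 ± 0.38, adjusted p = 0.0424) and Dbp (-2.12 ± 0.48, adjusted p = 0.0454) fell and Bhlhe41 rose (1.28 ± 0.30, adjusted p = 0.0415), and the list did not pass (camera, adjusted p = 0.0911; 0.418 with an estimated correlation).

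Fosl1 was higher in the libraries labelled Fra1KO, the reverse of what its deletion would give over deleted exons. Dilution by fewer acinar transcripts is argued against: over library totals, the Fosl1 change exceeded the median of genes outside the enzyme list (0.92) by 1.37 ± 0.46 (SE). Taking off that median does much of what TMM does, so the value restates the call after TMM and adds no second line of evidence. An exchange of the group labels could give this direction; Ccdc85b, opposite the last Fosl1 exons, changed by -1.09 ± 0.19, in the direction a deletion that reached it would give under the labels as they stand, but 5.2% of genes fell as far and the extent of the deletion is not in the labels, so the exchange stays open. Transcripts of the deleted allele may still be counted over its remaining exons. Alone, that would not lift the count above that of the intact gene, unless such transcripts were also more abundant. Counts over remaining exons cannot be told apart because 4 exon blocks share 1 count. A response of cells that lack Fra1 stays open and untested.

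The fall of some acinar enzymes and the rise of some laminin, NF-kB and YAP/TEAD genes may be an effect of genotype, which was not tested apart from the groups. Past the threshold were 3 of 29, 12 of 26, 13 of 31 and 6 of 15 members, and none of these sets held with an estimated correlation. Handling was not tested, though the dissociation stress set lay higher (camera, adjusted p = 0.00061; 0.352 with an estimated correlation). The sex of 1 sample was not settled by a test. Among the 5 male libraries, the enzyme score differed by -1.97 ± 0.82 (SE), but so few libraries leave that standard error uncertain. Without the female library, Fra1KO replicate 1, the median log2 fold changes of the enzyme, laminin, NF-kB and YAP/TEAD lists were -1.51, 1.3, 1.205 and 1.21. The direction of the pattern thus did not rest on that library. Macrophages in the sort, which the YFP gate should remove, cannot be told apart for the laminin, NF-kB and YAP/TEAD lists together. The NF-kB and YAP/TEAD scores rose by 0.70 ± 0.23 and 0.57 ± 0.25 (SE) more than the macrophage markers, but the laminin score by 0.62 ± 0.34, or 1.84 standard errors, and Lyz2 stood at 127 against 82.8 CPM. The enzyme score fell by 1.82 while the marker score rose by 0.47. Added macrophages would give that fall only if they made up much of the sort. As many genes as the 1063 changed were found in 1 of the 10 divisions of the 6 samples into 3 and 3, the real one, with 0 in each of the others (edgeR; 113 to 954 at an unadjusted p under 0.05), and as many lists as the 17 called in 2, with 11 to 18 in the others. The splits are too few for a share under 0.05. Each other division also mixes both labels in each set. A difference between the groups then widens the spread within sets and holds down the number of changed genes.

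The set of 12 genes counted in one group and nearly absent in the other (over 8-fold between each pair of libraries, with the highest library above 2 CPM) held 8 processed pseudogenes, where 2.24% of the genes tested are such. A segment linked to the Fosl1 allele is argued against, since 0 of the 12 lay on chromosome 19. Reads moved between a parent gene and its copy may account for some: Ftl1 fell while its copy rose, Rps2 and Atp6v0c had a sign opposite to that of their copies without passing (adjusted p = 0.27 and 0.141), and in 2 of these 3 families the summed CPM differed by less than 2 standard errors (887 ± 159 against 944 ± 64.9 for Rps2; SD, n = 3), but for Ftl1 and its copy it was 392 ± 61.2 against 750 ± 63.0, and the remaining genes were not tested. Genetic background that differs between the groups cannot be told apart from this, and need not be an alternative to it, since background could itself move reads. Pseudogenes were enriched (Fisher's exact test, p = 2.7e-11), but the enrichment restates what drew attention to the set, and moved reads would give it too. Single libraries were set apart from all others by over 8-fold too. Such genes numbered 7, 5 and 5 in Fra1KO replicates 1, 2 and 3, with the Y-linked Ddx3y among those of replicate 1. In Fra1WT replicates 1, 2 and 3 they numbered 3, 2 and 6, with the pseudogenes Rps24-ps3 and Rps13-ps1 among them. Differences of that size thus also occurred within a group. How much of the 1063 changes background or genotype carries stays open.

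Fra1KO replicate 3 had 14824 counts of the trypsinogen Try4 (chromosome 6, 41302269 to 41305532) against at least 519391 in any other library, and its neighbours Prss3 and Gm5771 had 868 and 366 against at least 29782 and 10135.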
